A study of Bos taurus with 8 samples.

How the data were processed

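MicroRNA was measured in mammary gland tissue of 8 heifers, 4 Holstein-Friesian and 4 Limousin, on one-colour Agilent bovine miRNA arrays. Per the labels' protocols, tissue was kept in RNAlater, total RNA with its small RNA was isolated with a miRNeasy kit, integrity was read on a Bioanalyser, and each sample was labelled with Cyanine 3-pCp and hybridised to its own array. Breed and replicate number were taken from the sample titles.

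Per the file headers, the scanner files were written by Agilent Feature Extraction 10.10.1.1, and the spot intensity used here was already corrected by the authors' software for a spatially fitted background, so that it can fall below 0. No normalization between arrays had been applied to these deposited intensities. The deposited value table of the series holds log2 values; its scale is not stated in the sources used here and was read from the values. Each of its columns equals the log2 of Agilent's total signal per miRNA, with 0.1 where a miRNA was not detected, minus a constant per array, to within 9.7e-06, and the 75th percentile of each column over the 784 rows, 21 of them controls, lay near 0. Its rows were not centred and its columns hold single samples, so no direction stays unknown; column medians ran from -9.79 to -8.53 because over 50% of the miRNAs sit at the value for undetected signals. That value lay 0.57 lower in Limousin than in Holstein-Friesian columns as a result of the scaling (log2 difference -0.57), so the table served as an alternative only, on the miRNAs detected here. The array annotation gives probe positions in UMD 3.1; positions are printed for the 1303 probes that map once and left out for the 354 that map to several places. miRNA names are those of the array design and can be old, and suffixes such as _v13.0 mark earlier sequences.

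Control spots and spots flagged as outliers were left out, and the 15 to 30 spots of a probe were averaged. A probe counted as detected on an array when more than 50% of its spots were well above background. Signals were divided by the array's 75th percentile over the probes detected on all 8 arrays and multiplied by the mean of that percentile over arrays, values under 1 were then set to 1, and log2 was taken. Each miRNA was represented by its probe with the highest mean; of 763 miRNAs, 670 had 2 probes, 55 had 3 and 38 had 4. A miRNA was detected where any of its probes was. The 270 miRNAs detected on all 4 arrays of at least 1 breed were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with breed as the only term and Benjamini-Hochberg adjustment at 0.05, and 463 miRNAs were detected on no array. Differences are Limousin minus Holstein-Friesian, following the series' design, which names Limousin as the test and Holstein-Friesian as the reference. For a miRNA below background on every array of a breed, the fold is a bound: the mean of the other breed against the mean of, per array, the higher of the lowest detected signal and the miRNA's own, and no fold is given where that bound is under 1. Signals of different probes were not set against each other.

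In all 21 lists of miRNAs (cell types, families, processes and a genomic cluster) were fixed before the data were examined, and 14 had at least 3 tested members. These were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and with fry. The miR-2284 and miR-2285 repeat list had 49 members on the array and 1 tested, miR-2285t, which fell; the skeletal muscle, smooth muscle, endothelial, erythroid, liver and neural, and miR-34 with miR-449 lists had 1 or 2 tested members and none past the threshold. The rule for the miRNAs that are named was also set beforehand: the 10 largest differences per direction past the threshold, the 2 members of each list with the smallest p, and up to 5 miRNAs per breed detected on all its arrays and on none of the other breed, by the size of the bound. It gave 51 miRNAs. Other members of lists, and the miRNAs in counts of 10 or fewer, were named after their values were seen. The number of miRNAs detected per array was compared with a two-sided exact permutation test.

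Alternatives set beforehand covered the scaling (75th percentile over all probes, quantile, median, none), the background (normexp with an offset of 50, or none), the summary of probes, the detection filter and floor, the deposited value table, the variance model, array weights, Student's test, the replicate number as a block, and leaving out each array. A correction of each array for probe GC content and length, alone and with the block, scaling to the labelling spike-ins and cyclic loess were added after the data were seen. Titles give both breeds the replicate numbers 1 to 4, and the second position index on the slide equals this number. The fitting steps were tested on simulated data of 270 miRNAs with 4 arrays per breed and 20 draws: changes of 0.5, 1 and 2 on the log2 scale were recovered for 63.5%, 94.0% and 99.2% of the changed miRNAs, and 3.15% of the calls were false. The simulated noise was independent between miRNAs and held no array-wide trend with GC content. The share of false calls therefore does not carry over to the calls in the real data. Figures and file reading used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.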

Results

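Small RNA was profiled in the mammary tissue of 8 non-pregnant heifers, 4 of the Holstein-Friesian dairy breed and 4 of the Limousin beef breed, with an age of 20 months in the sample characteristics and of 2 years in the labels' protocol. Holstein-Friesian cattle are kept for milk and Limousin cattle for meat, and the comparison asks how the microRNA (miRNA) content of the gland differs between the breeds in animals that have not calved. Each animal had its own one-colour Agilent array, and the labels call the 4 samples of a breed biological replicates. An array carried 45780 spots of 1657 probes for 763 bovine miRNAs, and between 28.6% and 35.5% of these spots were well above background. No spot was saturated. The 8 arrays lay on 1 slide and were read in 1 scan, with every Holstein-Friesian sample in the first and every Limousin sample in the second position index, so that slide position and breed cannot be told apart. The number of arrays limits the precision of each value. Across the 270 miRNAs detected on all 4 arrays of at least 1 breed, Pearson's r between arrays, taken over miRNAs that are not independent replicates, was 0.969 to 0.991 within Holstein-Friesian, 0.992 to 0.995 within Limousin and 0.949 to 0.983 between breeds. The first principal component, with 65.7% of the variance, parted the breeds, and the second, with 16.2%, set Holstein-Friesian replicate 2 apart at a score of -6.41.

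The miRNA with the largest increase in Limousin was miR-204, which in mammals lies within an intron of TRPM3. Its scaled log2 signal was 9.93 ± 0.19 (SD, n = 4) in Limousin and 7.53 ± 0.16 (SD, n = 4) in Holstein-Friesian, which is 5.29-fold higher (95% confidence interval 4.31 to 6.50; limma adjusted p = 1.2e-06). The probe, AGGCATAGGATGACAAAGGG, maps to chromosome 8 from 47259564 to 47259582 in UMD 3.1, as the array annotation gives it. Also higher in Limousin were miR-155, from the list of leukocyte miRNAs, 1.94-fold (1.57 to 2.39; limma adjusted p = 0.0012; chromosome 1 from 10227285 to 10227301), and miR-146b, from the stem and progenitor list, 1.92-fold (1.56 to 2.36; limma adjusted p = 0.0012; chromosome 26 from 22930919 to 22930938). The miRNA miR-21-5p, which is abundant in many dividing tissues, rose 1.75-fold (1.30 to 2.37; limma adjusted p = 0.0102). The collagen-targeting miR-29b rose 1.78-fold (1.34 to 2.38; limma adjusted p = 0.0074). After the correction for probe GC content and length described below, the calls of miR-21-5p and miR-29b ended: their log2 differences went from 0.81 to 0.41 and from 0.84 to 0.35 (adjusted p = 0.0971 and 0.168). The call of miR-146b stayed, but its difference went from 0.94 to 0.48. The entry miR-218_v13.0, an older database sequence of miR-218 with a probe on chromosome 20 from 2621245 to 2621263, rose 1.83-fold (1.51 to 2.22; limma adjusted p = 0.0012), and its log2 difference went from 0.88 to 0.50 after that correction. The other miRNAs among the 10 largest increases, miR-218, miR-29d, miR-192 and miR-132, were well above background on all 4 Limousin arrays but on 0, 0, 0 and 1 of the 4 Holstein-Friesian arrays. Their limma adjusted p was 0.0012, 0.0089, 0.0018 and 0.0107, and for miR-218, miR-29d and miR-192 the detection limit of the Holstein-Friesian arrays allowed no fold. All 4 turned past the threshold in the opposite direction when no background correction was made (adjusted p = 0.0430, 0.0171, 0.0226 and 0.0377). Background left in a signal is then divided by a larger factor on the brighter Limousin arrays, which can lower weak signals there. The sign also changed for miR-218, miR-29d and miR-192 with the floor at the lowest detected probe. One of the 2 probes of miR-29d went the opposite way, and the miRNA no longer passed after the GC and length correction (adjusted p = 0.0761). The probes of miR-218 and miR-218_v13.0, and those of the miR-29 members, have close relatives on the array, so their separate values are uncertain.

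Among the miRNAs that were lower in Limousin, miR-2413 had a log2 difference of -2.43 (SE 0.42, 4 arrays per breed), and its values spread more widely in Holstein-Friesian (SD 1.01, n = 4) than in Limousin (SD 0.33, n = 4). It was 5.40-fold higher in Holstein-Friesian (95% confidence interval 2.83 to 10.3; limma adjusted p = 0.0030), with its probe on chromosome 3 from 33702871 to 33702882. A member of the large bovine miR-2284 and miR-2285 repeat family, miR-2285t, was well above background on all 4 Holstein-Friesian arrays and on 0 of the 4 Limousin arrays. It was at least 4.45-fold higher in Holstein-Friesian, taking the mean of its signal there against the Limousin mean of the lowest detected signal per array (limma adjusted p = 4.4e-04). Holstein-Friesian replicate 2, at 6.85 against 5.53 to 5.70 in the others, raises that mean, and the bound would be lower without it. When 1 array was left out the fitted log2 difference ran from -2.52 to -2.08. This bound rests on 1 of its 2 probes, with a log2 difference of -2.40. The other, shorter one went the same way, but only by -0.83 (SE 0.48). The 2 cannot be compared while the Limousin signal is not above background. Also higher in Holstein-Friesian were miR-1247-3p, 2.82-fold (1.67 to 4.76; limma adjusted p = 0.0080; chromosome 21 from 68149492 to 68149502), miR-1434-3p, 2.75-fold (2.11 to 3.57; limma adjusted p = 5.4e-04), and miR-2410, 2.46-fold (1.78 to 3.40; limma adjusted p = 0.0024; chromosome 29 from 51051789 to 51051802). The miR-30 family member miR-30f was 2.19-fold higher in Holstein-Friesian (1.70 to 2.82; limma adjusted p = 0.0012; chromosome 9 from 10730950 to 10730965). Of the rest of the 10 largest decreases, miR-1584-5p, miR-2305 and miR-3141 were 2.22-fold, 2.16-fold and 2.15-fold higher in Holstein-Friesian, with limma adjusted p of 0.0183, 0.0035 and 0.0030; the call of miR-1584-5p ended after the GC and length correction (log2 difference -0.55; adjusted p = 0.0979), while miR-2305 went from -1.11 to -0.48, miR-3141 from -1.10 to -0.63 and miR-1247-3p from -1.49 to -0.92, all still past the threshold. The estimate of 2.39-fold for miR-763 rests on 1 of its 2 probes, since the other went the opposite way, and the miRNA was detected on 2 of the 4 Limousin arrays. These folds depend on the scaling. Without it miR-2413 still passed, at a log2 difference of -1.58, as did miR-2285t. The other 8 miRNAs of this paragraph then lay between -0.64 for miR-1247-3p and -0.25 for miR-3141, with miR-30f at -0.28, and did not pass.

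**Figure D1:**
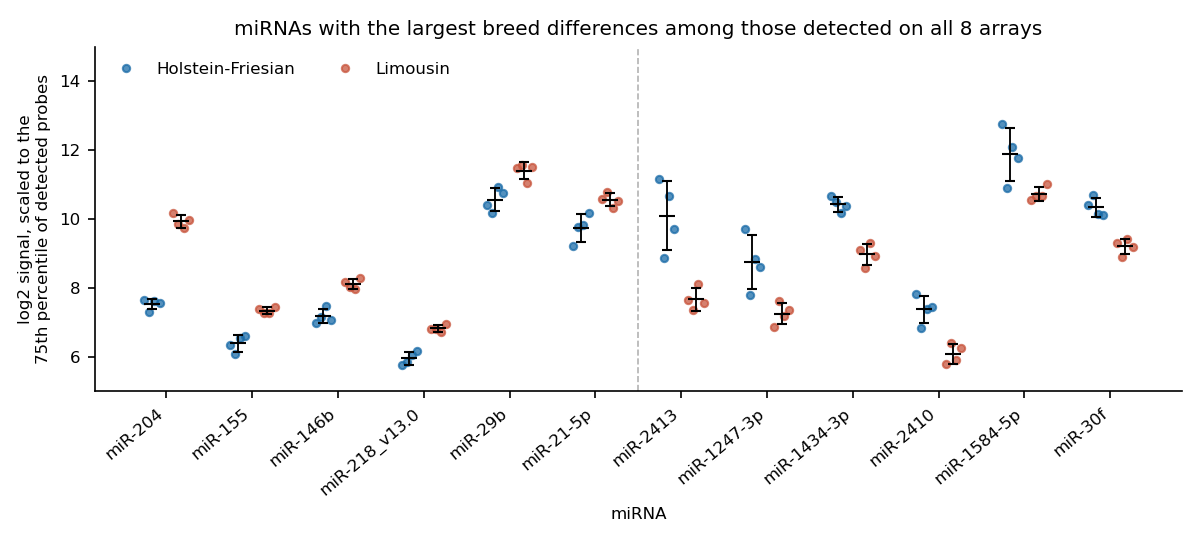
Scaled log2 signal (vertical axis) of 12 miRNAs (horizontal axis) that were detected on all 8 arrays, with the 6 largest increases in Limousin to the left of the dashed line and the 6 largest decreases to its right. Each point is 1 array, blue for Holstein-Friesian and red for Limousin, and black bars give mean ± SD (n = 4); miR-204 lies at 9.93 ± 0.19 in Limousin and 7.53 ± 0.16 in Holstein-Friesian.

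In all, 113 of the 270 tested miRNAs differed between the breeds (limma, Benjamini-Hochberg adjusted p under 0.05), 37 higher and 76 lower in Limousin. The 2 breeds did not overlap for 99 of the 270, where chance separates 4 arrays from 4 for 2.86% of miRNAs on average. That average gives no spread, and miRNAs that move together on the same arrays can separate together. All probes of the miRNA moved the same way for 108 of the 113, but probes of a miRNA can share nearly all of their sequence, as those of miR-204 do. The difference went with the GC content of the probes. Among the 68 tested miRNAs with the lowest probe GC content 18 rose and 3 fell. Of the 68 with the highest, 2 rose and 43 fell. Spearman's rho of the log2 difference with GC content was -0.64 across the 270 miRNAs (95% bootstrap interval -0.71 to -0.56), and miRNAs are not independent replicates. GC-rich probes were mostly the shorter ones, and this rho does not separate GC content from length. Directions are relative to the scaling, because the Limousin arrays were brighter: without scaling the median log2 difference was 0.78, and 173 miRNAs were higher and 2 lower. Under all 7 scalings tried, 36 of the 37 increases passed the threshold, while of the 76 decreases only miR-2413 and miR-2285t did. This contrast is partly built in, since the 7 include no scaling and spike-in scaling, the latter with 173 higher and 4 lower. The background settings were not among the 7. After a correction for probe GC content and length 51 of the 113 calls held. At 50% GC it took more off the longer probe: miR-204 (20 bases) went from 2.40 to 2.07 and miR-145 (18 bases) from -0.23 to -0.37. At 15 bases it was nearly alike for miR-2410 (60% GC), from -1.30 to -1.09, and miR-30d (66.7% GC), from -0.54 to -0.31. Length thus weighed more than GC content in this correction, so the pattern is not one of base composition alone. Of the calls that passed under all 7 scalings, 16 increases and 2 decreases also held after this correction. The count fell to 71 without Limousin replicate 1 and to 74 without Holstein-Friesian replicate 4.

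**Figure D2:**
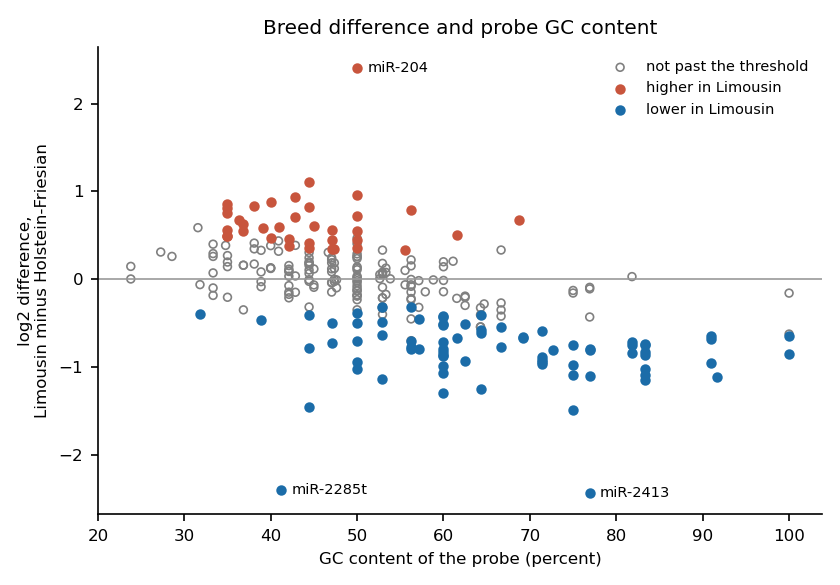
Log2 difference between the breeds, Limousin minus Holstein-Friesian (vertical axis), against the GC content of the probe in percent (horizontal axis) for the 270 tested miRNAs. Red and blue points passed the threshold and open points did not; the differences fall as GC content rises (Spearman's rho -0.64), and miR-204 and miR-2285t lie away from this trend.

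Lists of miRNAs fixed in advance described the tissue by function, family and cell type. Of the 16 tested miRNAs linked to mammary development and lactation, 8 rose in Limousin, 1 fell and 7 did not pass. Those that rose included miR-101, by 0.76 on the log2 scale (limma adjusted p = 0.0036), miR-21-5p, miR-29b, miR-15a, by 0.46, and miR-221, by 0.45 (limma adjusted p = 0.0094). The member that fell was miR-181a, with a log2 difference of -0.51 (limma adjusted p = 0.0151). In the miR-29 family, known for repressing collagen genes, the 3 members detected in both breeds rose, miR-29a by 0.60, miR-29b by 0.84 and miR-29c by 0.67. The fourth, miR-29d, passed as well, but its direction is uncertain, since it was not well above background on any Holstein-Friesian array and its 2 probes disagreed. In the let-7 family, regulators of developmental timing, let-7i and let-7e rose, by 0.70 and 0.38 (the call of let-7e was lost without 1 of 3 arrays, with limma adjusted p up to 0.0670), and 8 of the 10 tested members did not pass. The list tied to estrogen and insulin signalling had 3 members that rose, miR-222, by 0.50 (limma adjusted p = 0.0066; chromosome X from 103538218 to 103538229), its neighbour miR-221 and miR-29a, and 13 of the 16 tested that did not pass. In the stromal fibroblast list 5 of 14 rose, miR-199b by 0.59 (limma adjusted p = 0.0089), 2 arms of miR-199a, miR-424-5p by 0.55, and miR-218. This entry of miR-218 was below detection in Holstein-Friesian. The entry miR-218_v13.0, outside the list, was detected on all 4 arrays of each breed. Within these 5 lists alone, the counts adjusted over the list alone were again 8 higher and 1 lower, then 4, 2, 3 and 5 higher. Between 2 and 14 of the tested members of each of these lists also belong to another list. The difference of miR-101 went to 0.36 after the GC correction (adjusted p = 0.0288). Many of these calls ended after the correction for GC content and length: 4 of 9 stayed in the mammary list (miR-101, miR-221, miR-132 and miR-24-3p), 0 of 4 in miR-29, 0 of 2 in let-7, 2 of 3 in the estrogen and insulin list (miR-221 and miR-222) and 1 of 5 in the stromal list (miR-218). Of these, miR-132 and miR-218 turned direction without background correction, as said above. The adjusted p was then 0.165 for miR-15a, 0.0590 for miR-181a, 0.305 for miR-29a, 0.732 for miR-29c, 0.128 for let-7i and 0.365 for let-7e. In the stromal list miR-199b went from 0.59 to 0.017 (adjusted p = 0.901), miR-199a-3p from 0.47 to 0.091 (0.465), miR-199a-5p from 0.36 to 0.20 (0.112) and miR-424-5p from 0.55 to 0.26 (0.0651). The entry miR-199c, outside the list and looked at afterwards, has a probe of 17 bases that lies within the 20 of miR-199a-3p. It rose by 0.56 (limma adjusted p = 0.0066) and stayed at 0.52 (adjusted p = 0.0080). What is left of the miR-199 rise thus depends on the probe.

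Relative to the other tested miRNAs, these 5 lists shifted upward in limma's camera test, with adjusted p of 0.0039 for mammary development and lactation, 0.0161 for miR-29, 0.0180 for let-7 and for estrogen and insulin signalling, and 0.0331 for stromal fibroblasts. None held with an estimated correlation (adjusted p = 0.507 for each of the 5). The stromal list, whose median of 0.04 rests on 5 members that rose and 9 that did not pass, was lost without Holstein-Friesian replicate 2 (camera adjusted p = 0.0914; median -0.06) and without Limousin replicate 1 (0.0546). The mean probe GC content was 45.8% in the mammary list, 38.6% in miR-29, 39.0% in let-7, 46.3% in the estrogen and insulin list and 47.8% in the stromal list. After the correction for GC content and length, the mammary list kept an adjusted p of 0.0448 and the other 4 lay between 0.227 and 0.705; the let-7 shift then turned downward.

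**Figure D3:**
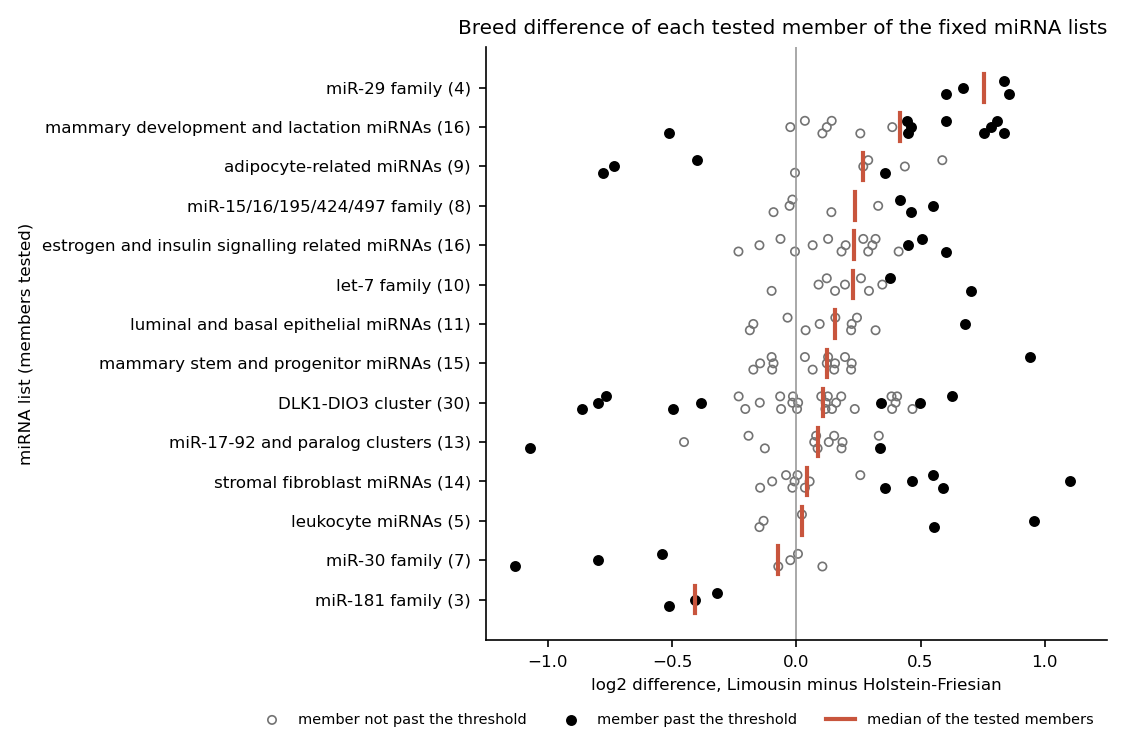
Log2 difference between the breeds, Limousin minus Holstein-Friesian (horizontal axis), of each tested member of the 14 lists with at least 3 tested members (vertical axis, number of tested members in parentheses). Filled points passed the threshold, open points did not, and red bars mark list medians; all 4 points of the miR-29 family lie above 0, one of them, miR-29d, with no Holstein-Friesian signal above background, and all 3 of the miR-181 family below, although these 3 lie above 0 without scaling.

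Other lists showed members moving both ways or few past the threshold. All 3 tested members of the miR-181 family fell, miR-181a, miR-181b, with a log2 difference of -0.41, and miR-181d, and 3 of the 7 tested members of the miR-30 family fell, miR-30f, miR-30a-5p and miR-30d, the last at -0.54 (chromosome 14 from 8080307 to 8080320). Without scaling all 3 miR-181 members, miR-30a-5p and miR-30d changed sign. Neither family passed camera (adjusted p = 0.156 and 0.232), and both passed fry, which asks whether members move one way on balance (adjusted p = 0.0204 for each). In the miR-15 and miR-16 seed family 3 of 8 rose, among them miR-15a and miR-424-5p (4 when adjusted over the list alone; camera adjusted p = 0.0744). Among the miR-17-92 clusters and paralogs miR-363, on chromosome X from 17917759 to 17917772, fell, with a log2 difference of -1.07 (limma adjusted p = 0.0035; -0.22 without scaling, adjusted p = 0.530), miR-25 rose by 0.33 (adjusted p = 0.0403), and 11 of 13 did not pass (camera adjusted p = 0.411); adjusted over the list alone, only miR-363 passed. The median of that list was 0.09 and its mean -0.02, and the median ran from -0.0067 to 0.22 when 1 array was left out. Of 30 tested miRNAs of the imprinted DLK1-DIO3 cluster, 3 rose and 5 fell, with miR-665 at -0.86 and miR-370 at -0.77 (camera adjusted p = 0.232; 1 rose and 5 fell adjusted over the list alone). Without scaling 4 of the 5 changed sign (miR-370, miR-380-3p, miR-487a and miR-494) and miR-665 was at -0.010. One of the 3 that rose was miR-1185, at least 1.03-fold higher in Limousin against the Holstein-Friesian detection limit (limma adjusted p = 0.0320), but at a log2 difference of -0.38 without background correction (adjusted p = 0.0323). The calls of miR-25, miR-181b, miR-15a and miR-1185 were each lost when 1 of 3 to 7 arrays was left out (limma adjusted p up to 0.114). Of the calls in this paragraph, miR-30f, miR-181d, miR-363, miR-370, miR-380-3p and miR-487a stayed after the correction for GC content and length. Those of miR-181a, miR-181b, miR-30a-5p, miR-30d, miR-15a, miR-16b, miR-424-5p, miR-25, miR-376b, miR-409a, miR-494, miR-665 and miR-1185 ended, with adjusted p from 0.0571 for miR-30a-5p to 0.546 for miR-181b. A lost call need not mean a lost difference: miR-30a-5p stayed at -0.59 of -0.80, miR-181a at -0.31 of -0.51 and miR-30d at -0.31 of -0.54, while miR-181b was left at -0.081 and miR-665 at -0.26. The entry miR-181b_v12.0, whose probe is that of miR-181b with 1 more base, went from -0.43 (limma adjusted p = 0.0141) to -0.22 (adjusted p = 0.0935). The only tested member of the miR-34 and miR-449 family, miR-34a, had a log2 difference of 0.26 (limma adjusted p = 0.386).

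Markers of cell types gave the following values. In the leukocyte list miR-155 and miR-142-5p rose, the latter by 0.56 (limma adjusted p = 0.0223, and up to 0.0671 without 1 of 4 arrays), and the other 3 of 5 did not pass (camera adjusted p = 0.230). The call of miR-142-5p ended after the GC and length correction (log2 difference 0.16; adjusted p = 0.342), as did that of miR-27b below (0.22; adjusted p = 0.0843). Of 11 tested epithelial miRNAs only miR-375 passed; it was well above background on all 4 Limousin and 0 of 4 Holstein-Friesian arrays (limma adjusted p = 0.0066). Its direction turned, past the threshold, with the floor at the lowest detected probe (-0.40; adjusted p = 0.0387) and without background correction (-0.46; adjusted p = 0.0189). miR-96 had a log2 difference of 0.32 (adjusted p = 0.112; camera adjusted p of the list 0.177); it passed without Holstein-Friesian replicate 2 (0.43; adjusted p = 0.0186) and lay at -0.25 after the GC correction. In the stem and progenitor list miR-146b rose and the other 14 of 15 did not pass, with let-7a-5p at 0.20 (adjusted p = 0.179; camera adjusted p of the list 0.173). In the adipocyte-related list miR-378b fell, with a log2 difference of -0.78 (limma adjusted p = 0.0036), as did miR-378c, at -0.73, and miR-365-3p, while miR-27b rose (1 rose and 3 fell of 9; camera adjusted p = 0.548; list median 0.27, list mean 0.0028). Without scaling the 3 that fell changed sign. The smooth muscle miRNAs miR-145 and miR-143 had log2 differences of -0.23 and -0.06, the endothelial miR-126-5p and miR-126-3p of 0.41 and 0.20, the erythroid miR-451 of -0.35, the muscle miRNA miR-1 of 0.26 and the neural miR-128 of -0.03, none past the threshold in this fit. Other fits changed some of these: miR-145 passed after the GC correction (-0.37; adjusted p = 0.0171), and miR-126-5p passed without Holstein-Friesian replicate 2 or 4 (adjusted p = 0.0454 and 0.0498) but lay at -0.071 after the GC correction. miR-143, miR-145, miR-128 and miR-451 changed sign without scaling. Of these, miR-143, miR-145 and miR-128 then passed as higher in Limousin (limma adjusted p = 0.0133, 0.0495 and 0.0097), in a fit that called 173 miRNAs higher.

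More miRNAs were detected in Limousin than in Holstein-Friesian tissue. The Limousin arrays detected 281 ± 11.9 miRNAs (SD, n = 4) and the Holstein-Friesian arrays 256 ± 10.05 (SD, n = 4), a difference of 25.5 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 can give). In total 232 miRNAs were detected on all 8 arrays. Another 9 were detected on all 4 Limousin arrays and no Holstein-Friesian array, namely miR-192, miR-218, miR-29d, miR-375, miR-1185, miR-33a, miR-21-3p, miR-885 and miR-30b-3p, and 1, miR-2285t, showed the opposite. Being detected in Limousin only need not mean a higher level there. For miR-33a, encoded within SREBF2 in mammals, no fold could be given (limma adjusted p = 0.252). Its log2 difference was 0.39, and those of miR-21-3p, miR-885 and miR-30b-3p were 0.14, -0.08 and -0.02 (limma adjusted p = 0.606, 0.667 and 0.874). The rest, miR-192, miR-218, miR-29d, miR-375 and miR-1185, passed. Of the 9, only miR-1185 allowed a fold against the detection limit. The Limousin arrays were also brighter, by 0.85 in the log2 75th percentile of the detected probes (95% confidence interval 0.30 to 1.40; exact permutation p = 0.0286, adjusted 0.0857 over 6 array measures), so detection counts and brightness moved together. With any spot of a probe sufficing, the breeds differed by 57.25 miRNAs (472 against 415; exact permutation p = 0.0286). When all spots of a probe had to be well above background the exact permutation p of the detection count was 0.0571, and with Agilent's own flag it was 0.0857. The difference was 21.25 without Holstein-Friesian replicate 2 (exact permutation p = 0.0857), and 20.25 without Limousin replicate 2 and 24.6 without Limousin replicate 4 (exact permutation p = 0.0571 for each).

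**Figure D4:**
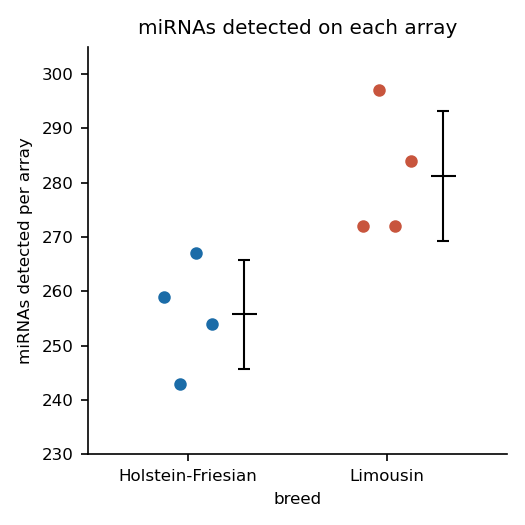
Number of miRNAs detected on each array (vertical axis, which does not start at 0) for the 2 breeds (horizontal axis). Points are arrays and black bars give mean ± SD (n = 4); the 4 Limousin arrays lie between 272 and 297 and the 4 Holstein-Friesian arrays between 243 and 267.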

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

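The tests of labelling, hybridization and slide position, and those of miR-204 and miR-2285t taken one by one against a GC trend and 1 array, were chosen after the results were seen. Of 116 groups of 4 values checked, 3 held a value far from the other 3, where chance gives about 5.8. They were miR-29b in Limousin, with replicate 3 at 11.04 against 11.49 to 11.56, miR-192 in Holstein-Friesian, with replicate 3 at 4.02 against 3.57 to 3.63, and miR-2285t in Holstein-Friesian, with replicate 2 at 6.85 against 5.53 to 5.70.

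The count of 113 miRNAs was not matched by any other grouping of the 8 arrays into 4 and 4. Only 1 of the 35 splits, the real one, gave a count as large, and the highest other was 0. This argues against chance but cannot exclude it, since 1 of 35 is the smallest share these splits can give. All other splits mix the breeds, so a shift shared by many miRNAs widens the spread within their groups and can lower their counts. The 113 miRNAs are therefore not independent support. For the lists chance stays open, since 10 of the 35 splits gave at least the 5 lists of the real one. The highest other split gave 8 lists.

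Relative to the scaling, the breed difference fell as GC content rose: 18 of the 68 miRNAs of lowest GC content rose and 3 fell, and of the 68 of highest GC content 2 rose and 43 fell. Without scaling the medians of these 2 groups were 1.05 and 0.20, both above 0. Weak signals near the detection limit are argued against by Spearman's rho of -0.6641 with GC content among the 135 miRNAs above the median signal. The rho of -0.6418 without the scaling does not test the scaling, since one factor per array shifts all miRNAs alike and can hardly change their ranks. After each array was corrected for probe GC content and length, 51 of the 113 miRNAs stayed past the threshold in the same direction. This is under 50%. The test, set before it was run but after the data were seen, took that as the mark of a trend with GC content and length as the whole cause of the calls. That bound cannot show a whole cause, since 78 miRNAs still passed in the corrected fit. A linear trend could account for a part of the calls. Over all 113 the median absolute difference went from 0.72 to 0.41 and the median standard error from 0.17 to 0.13, and over all 270 tested miRNAs from 0.33 to 0.25 and from 0.15 to 0.13. What lies behind the 51 stays open, since they were picked by passing after the correction. Whether the trend comes from breed, RNA quality or slide position cannot be told apart, because 0 of the 2 sides of the slide held both breeds, and trends of up to rho -0.73 also arose between arrays of Limousin alone.

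The Limousin arrays were brighter by 0.85 on the log2 scale and detected more miRNAs. Weaker labelling of the Holstein-Friesian RNA is argued against by the labelling spike-ins, which differed by 0.06797 (95% confidence interval -0.19 to 0.32), and weaker hybridization by its spike-ins, at 0.04144 (-0.17 to 0.25); spike-ins do not test the quality or amount of the sample RNA. A constant dilution of miRNA would shift all miRNAs alike. Without scaling the 68 miRNAs of lowest and the 68 of highest GC content differed by 0.8471 (95% bootstrap interval 0.71 to 1.03). That interval treats miRNAs as replicates and gives no spread between animals. In these arrays the difference argues against dilution acting alone. The unscaled medians of the 2 groups, 1.05 and 0.20, lay above 0, so dilution together with the trend in GC content and length stays open. The place on the slide cannot be told apart from breed, since 0 sides held both, and a difference between the breeds stays open and untested.

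The miRNAs miR-204 and miR-2285t differed in ways that the linear trend with probe GC content and length does not account for. After the GC and length correction miR-204 kept a log2 difference of 2.067 of 2.40, which argues against that trend. It passed in all 8 fits that left out 1 array, which argues against the weight of 1 array. Its other probe showed 103.2% of the difference, which met the prediction against a fault of 1 probe. That probe is the same sequence without the last base, however. A fault of the shared sequence would show in each of the 2 probes and stays open. For miR-2285t, not above background in Limousin, only the bound of 2.15 below Holstein-Friesian (standard error of that mean 0.31) can be used. The trend gives its probe 0.06653, in the other direction, so the trend does not explain it. In addition, 4 of the 4 Holstein-Friesian arrays lay above the highest Limousin detection limit of 4.08. Detection there already fixed this outcome, since the lowest detected signals of these arrays were 4.33 to 4.91. The lowest Holstein-Friesian signal of miR-2285t, 5.53, lay above all these limits, which argues against the weight of 1 array for the direction. The size of the bound is raised by replicate 2, at 6.85. The other probe of miR-2285t showed a smaller log2 difference, -0.83 (SE 0.48) against -2.40, so it gives no second support for the size. A fault of 1 probe stays open for miR-2285t, since 0 Limousin arrays had the signal needed to compare its probes. Other miRNAs kept large differences after the correction, such as miR-2413 at -1.96 (adjusted p = 0.0049) and miR-1434-3p at -1.61 (adjusted p = 2.3e-04), and were not tested further. A breed difference in miR-204 and miR-2285t remains a hypothesis, and slide position is open for both.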

How the results depend on the processing

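The GC and length correction, alone and with the replicate block, the spike-in scaling and cyclic loess were chosen after the data were seen. The count of 113 miRNAs, 37 higher and 76 lower in Limousin, stayed within 1.5 times under most alternatives, but its split by direction depended on the scaling. It was 175 (173 and 2) without scaling, 177 (173 and 4) with spike-in scaling, 104 higher and 30 lower with the percentile over all probes, 81 and 28 with the deposited value table, 55 and 43 with quantile normalization, 57 and 44 with normexp, 40 and 59 with the median, 48 and 58 with cyclic loess, 44 and 56 with the total miRNA signal, and 170 (27 and 143) without background correction. The median log2 difference of all tested miRNAs moved with it, from -0.07 to 0.78 without scaling, 0.72 with spike-in scaling, 0.26 with all probes and -0.36 without background correction. Without scaling and with spike-in scaling, brighter Limousin arrays by construction count as higher miRNAs. Without background correction, the background left in a signal is divided by a larger factor on the brighter arrays. This can lower weak signals in Limousin by construction, and its share of the downward move was not measured. With array weights the count was 152, with the GC and length correction 78, and with Student's test 129 unadjusted and 81 adjusted (48 lower). Leaving out 1 array gave 71 to 150 miRNAs (24 to 57 higher, 47 to 93 lower), with 71 without Limousin replicate 1, 74 without Holstein-Friesian replicate 4 and 150 without Holstein-Friesian replicate 2, which stands apart. The 5 lists became 8 without the detection filter, where more members were tested, and 7 without background correction. They were 4 with the percentile over all probes and with the deposited value table, where miR-29 was lost. With quantile normalization, array weights and detection on all arrays they were also 4, without the stromal list. They became 3 with the floor at the lowest detected probe, 2 without scaling and with spike-in scaling, and 1 with cyclic loess and with the GC correction. With an estimated correlation 0 were left, and 4 to 6 when 1 array was left out. The 10 miRNAs detected in one breed became 3 when any spot sufficed, 6 with Agilent's flag, and 10 to 15 when 1 array was left out. When any spot sufficed, and with Agilent's flag, 0 were detected in Holstein-Friesian only, so miR-2285t dropped out. The difference of 25.5 detected miRNAs per array was 57.25 when any spot sufficed (472 against 415; exact permutation p = 0.0286), 27.75 when all spots were required (exact permutation p = 0.0571), 23.25 with Agilent's flag (exact permutation p = 0.0857), and 20.25 to 29.25 when 1 array was left out, no longer past the threshold without Holstein-Friesian replicate 2, Limousin replicate 2 or Limousin replicate 4. Signal over background limits the values of miRNAs detected in one breed. Where no cause is named, the cause was not tested.

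Several named miRNAs changed sign. Without scaling, and in parentheses with spike-in scaling, the log2 difference became 0.62 (0.55) for miR-145, 0.79 (0.72) for miR-143, 0.51 (0.44) for miR-451, 0.077 (0.0086) for miR-378b, 0.12 (0.054) for miR-378c, 0.83 (0.76) for miR-128, 0.31 (0.24) for miR-30d, 0.34 (0.27) for miR-181a, 0.45 (0.38) for miR-181b and 0.087 (0.019) for miR-370. For miR-143 it was 0.27 with all probes, 0.079 with quantile normalization, 0.018 with the median, 0.061 with normexp, 0.22 with the deposited value table, 0.044 with cyclic loess and 0.029 with the GC correction. For miR-128 it was 0.30, 0.17, 0.055, 0.083, 0.21 and 0.18 under the first 6 of these and 0.028 with array weights, and -0.093 to 0.019 when 1 array was left out. For miR-145 it was 0.10 with all probes and 0.011 with the deposited value table, and for miR-451 it was 0.25 with array weights and -0.61 to 0.13 when 1 array was left out. Without background correction, which by construction can lower weak signals in Limousin, it was -0.36 for miR-218, -0.40 for miR-29d, -0.38 for miR-192, -0.33 for miR-132, -0.46 for miR-375, -0.40 for miR-1, -0.38 for miR-1185 and -0.48 for miR-33a, all at or near background in Holstein-Friesian, and the median of the DLK1-DIO3 list was -0.29. With the floor at the lowest detected probe, which is higher on the dimmer Holstein-Friesian arrays by construction, it was -0.20 for miR-218, -0.22 for miR-29d, -0.14 for miR-192, -0.40 for miR-375 and -0.25 for miR-33a. With the GC and length correction, with the same values in the replicate block, it was -0.25 for miR-96, -0.26 for miR-1, -0.071 for miR-126-5p, -0.20 for let-7a-5p, -0.078 for miR-34a and -0.079 for miR-33a, and the list medians were -0.14 for the adipocyte-related list, -0.16 for let-7 and -0.18 for DLK1-DIO3. With cyclic loess let-7a-5p was at -0.017. Under fry the direction of the adipocyte-related list, with its median of 0.27, was downward.

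The labels call the numbered samples biological replicates of separate animals, so the shared numbers were not taken as pairs. Deviations from the breed means correlated at -0.31, -0.25, -0.45 and 0.32 for numbers 1 to 4. These 4 values cannot decide on a pairing, since each number also stands for a row on the slide. With the replicate block, which also stands for the row on the slide, 84 miRNAs passed (25 higher and 59 lower) and 5 lists, and with the block and the GC correction 61 (20 and 41) and 1 list. Not every sample correlated best with its own number.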

Other observations

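Many of the miRNAs that fell in Limousin carry high database numbers, which are given in the order of naming. Of 58 tested miRNAs with the number of miR-2284 or a higher one, 0 rose and 37 fell, with a median log2 difference of -0.70, against 37 that rose and 39 that fell among the other 212. This group was chosen after its values were seen. Its probes had a mean GC content of 65.6% against 50.3% in the others, and without scaling its median difference was 0.15 against 0.89. After the correction for GC content and length 3 rose and 17 fell, against 23 and 35.

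Neighbouring miRNAs moved alike in some pairs and apart in others. On chromosome X both miR-222 and miR-221 passed, at 0.50 and 0.45, while on chromosome 12 miR-15a passed at 0.46 and miR-16a, at 0.33, did not (limma adjusted p = 0.0519). Members of other pairs had opposite signs, with miR-199b at 0.59 beside miR-3154 at -0.42 and let-7e at 0.38 beside miR-125a at -0.35; miR-3154 and miR-125a did not pass. On chromosome 21, in the DLK1-DIO3 cluster, members went both ways. Among 138 pairs of miRNAs within 10 kb on the same strand, the median absolute difference within a pair was 0.32, against 0.51 in shuffled pairs (permutation p = 0.0067). Shared transcription may be a reason, but after the correction for GC content and length the medians were 0.29 and 0.37 (permutation p = 0.0877). The prediction set before this test took a p of 0.05 or more as evidence against it; that bound was wrong, since a missed threshold excludes nothing, and the question stays open. Without chromosome 21, a choice made after the result was seen, 39 corrected pairs gave a permutation p of 0.0105.

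The deposited value table shows how a fixed value for undetected signals acts after scaling. Over all its 763 miRNAs, 550 passed the threshold of the same limma test, and these included all 425 miRNAs that Agilent's flag called detected on no array. Their differences are those of the array constants, since undetected signals were set to 0.1 before the arrays were scaled. The other 125 were flagged as detected on at least 1 array.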
